A study of Arabidopsis thaliana with 10 samples.

How the data were processed

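Total RNA from pooled frozen leaf tissue of Arabidopsis thaliana, accession Columbia, was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are log2 expression values per probe set made by the authors with RMA, per the submitters' processing notes. RMA corrects background, normalises the arrays to 1 distribution and summarises the probes of a set. Its version and settings are not given in the sources used here. The deposited log2 values carry 1 decimal, so differences between single arrays come in steps of that size. The array medians lay between 5.5 and 5.7, and the values between 2.4 and 14.2. An array has no read depth, and the precision of each comparison is limited by the number of arrays. RMA values carry no detection call, so dim probe sets were not marked as absent. A limit chosen after seeing the data, the highest value of BAN and EXPA7 (3.9), genes not expected in leaves, marks named changes whose dim side reached it on at least 1 array as lower bounds.

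The series holds 10 arrays, 5 of plants carrying a 35S:PAP1 transgene and 5 of an empty vector control, with 1 array of each line on days 1, 2, 7, 8 and 12. The control arrays carry the label Hex, which was read as the empty vector because the series names only these lines and the other label is Pap. The labels give the day but not the growth regime of each array. From the series text, day 1 was read as the 22 °C regime at 440 µmol m-2 s-1, days 2 and 7 as the warm dim regime of 6 days (30 °C by day, 150 µmol m-2 s-1) and days 8 and 12 as the cool bright regime (15 °C, 440 µmol m-2 s-1). Comparisons between days hold whatever this reading. On this reading day, plant age and regime coincide, and temperature and light changed together, so the day and regime contrasts cannot tell their parts apart. No label names separate plants or cultures as replicates of a line on a day, so p-values measure the spread between these arrays, which holds technical error, plant-to-plant differences and unequal responses of the lines.

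Of 22810 probe sets, 64 array controls were left out and 22746 were tested. The probe table used here names 1 gene for 13513 probe sets (13350 genes, 13436 of the probe sets matched to the reference gene table by Entrez identifier) and several genes for 503. It does not list the remaining 8730, which are unnamed here. No probe set was named from memory. The PAP1 locus, AT1G56650, had 0 probe sets naming it alone, so the transgene's own transcript is not analysed here and could not serve as a check of the labels. The number of per-sample columns not used was 0.

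Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05 and no fold limit. The genotype effect was the 35S:PAP1 minus empty vector difference with day as a block (4 residual degrees of freedom). The day contrasts came from the same model, with 2 arrays on each day, 1 per line, and all 10 arrays giving 1 estimate of spread. The regime contrasts set the mean of days 2 and 7 against the mean of days 1, 8 and 12 within each line (6 residual degrees of freedom), so that days stand in for replicates. The interaction compared the 5 per-day differences between lines across regimes (3 residual degrees of freedom). The day in the label pairs the arrays. Deviations of same-day arrays from their line's mean correlated at 0.52, 0.77, 0.49, 0.84 and 0.75 on days 1, 2, 7, 8 and 12.

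The samples' groups, the models, the alternatives, the gene lists and the rule for named genes were set at the start. That rule takes up to 12 genes per direction for the genotype effect with the same sign on all 5 days, 8 per direction for each day contrast with the same sign in both lines, and 6 per direction for the regime contrasts and the interaction. It takes probe sets that name 1 gene and pass the threshold, ranked by size of change, and any list member may be named as well. Of several probe sets of a gene, the one with the highest mean stood for it. The rule named PAP1 first, which had no probe set of its own name.

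The 23 lists hold 229 members, of which 39 had a probe set naming 1 gene. For 36 of these the symbol and locus both matched the reference gene table, ignoring case, punctuation, an AT prefix and a trailing point and zero. The other 3, AT4G14090, AT1G06000 and AT1G53540, carried no matching symbol and were added only in an alternative. The 6 lists with at least 3 used members were tested: late anthocyanin genes, heat shock, cold response, light harvesting, senescence, and peroxidases. They held 4, 3, 5, 3, 3 and 3 used members in that order. Light harvesting was left with LHCB4.1, LHCB4.2 and LHCB4.3 alone, and no laccase planned beside the peroxidases was left. Most planned members of each list were missing, so a list result does not stand for its whole pathway. Members of lists with 1 or 2 used genes were read singly, and 4 lists had no used member. Markers of flowers and trichomes were among the latter, so these tissues were not checked. Lists were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusting over the 6 lists. Counts of members called over all probe sets stand beside counts adjusted over the list alone. The median difference between lines on each day was ranked among 10000 random lists matched on mean expression.

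The scripts were tested on simulated data in which 200 of the 22746 probe sets were changed, 100 at each size. For the genotype effect 98% of changes of 1 log2 unit and 99% of changes of 2 units were recovered, and 18 of 215 calls were false. For day 2 against day 1 these shares were 62% and 99%, with 13 false calls of 174. For the regime contrast in 35S:PAP1 they were 81% and 99%, with 10 false of 190, and for the interaction 9% and 92%, with 1 false of 102. Each simulated change had 1 size on all arrays it covered, with independent normal noise, whereas real differences between the lines varied by day. For the regime contrast all simulated days shared 1 baseline, whereas in the data differences between days of a regime are part of its spread. Its simulated shares thus say little about the real contrast. With 200 planted changes the adjustment is also milder than with the 18 genotype calls in the data. The shares recovered can therefore be too high for these data.

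Other choices, also fixed before the data were examined, were quantile normalisation, centring each array on its median, leaving out the dimmest 40% of probe sets, a trended robust variance prior, only probe sets naming 1 gene, leaving out each day or array, fits without the block or the line term, day as a random block, and stricter calls at 0.01 for the reversal. Those chosen after seeing the data were leaving out the 35S:PAP1 arrays of days 2 and 7, day 2 in place of day 7, noise within the rounding step, list members matched by locus alone, and tests of gene families by symbol.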

Results

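The series followed leaf gene expression in red-leaved 35S:PAP1 and in empty vector Arabidopsis plants through changes of growth regime. As read here, the last regime (15 °C) was colder than the first (22 °C), so it was not a return to the start. In 35S:PAP1 plants a constitutive viral promoter drives PAP1, a MYB transcription factor that activates anthocyanin genes. Per the series text, their leaves turned from red to largely green during 6 days of warm dim growth, and a cool bright regime was then used to bring the red back. Each of the 10 arrays measured 22746 probe sets, with 1 array per line on each of days 1, 2, 7, 8 and 12. There was no replicate of a line on a day.

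Control probe sets set some arrays apart. The poly-A controls, bacterial transcripts spiked in before labelling, had a median of 3.8 on the empty vector day 7 array and 3.85 on the 35S:PAP1 day 7 array, against 6.9 to 7.5 on the 8 arrays of other days. The hybridisation controls, added later, lay between 8.7 and 9.15 on all 10 arrays. On the 35S:PAP1 day 2 array the 25S ribosomal RNA probe set read 9.7, against 4.7 to 6.7 on the other 9. The 5′ minus 3′ difference of actin, which falls as RNA breaks down, was -2.5 on that array and -1.5 to -1.2 on the other 9. Over all probe sets, the lines correlated at 0.990, 0.986, 0.973, 0.991 and 0.988 on days 1, 2, 7, 8 and 12. PYK10 and EXPA7, which mark roots, read 4.1 to 5.1 and 3.5 to 3.9 across the arrays, and BAN, a seed coat gene, 3.3 to 3.7. With no detection call, changes of named genes that start or end at 3.9 or less, the highest of EXPA7 and BAN, are given as lower bounds. Medians of lists can hold such members. PYK10, which read higher, was not used for this limit. If its level were background too, further changes would be lower bounds. Those of UF3GT and AT4G14090, which read 5 and 4.7 in the empty vector on days 2 and 7, would be among them.

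**Figure D1:**
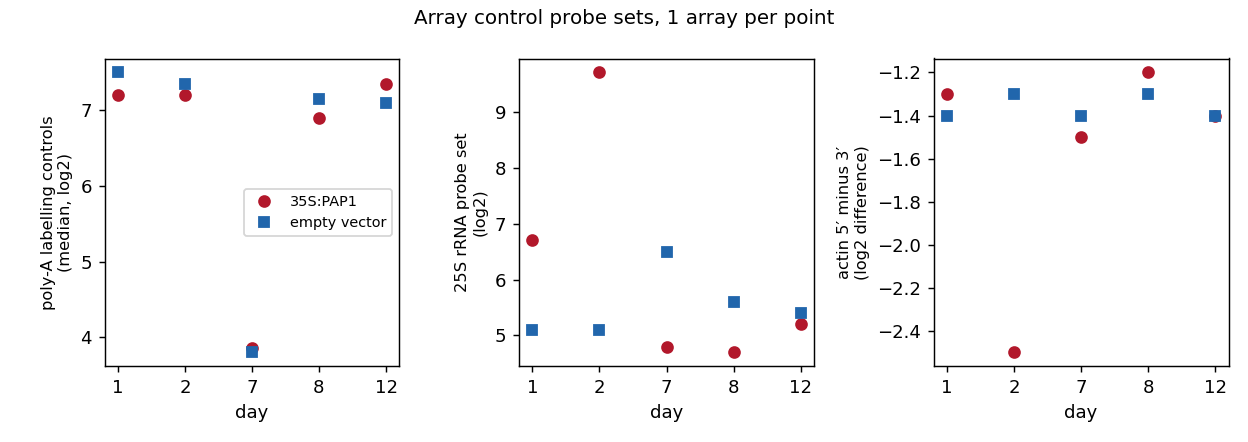
Control probe sets on each of the 10 arrays (log2 values): median of the poly-A labelling controls, the 25S ribosomal RNA probe set, and the actin 5′ minus 3′ difference, by day and line. The poly-A median lies at 3.8 and 3.85 on day 7, and the 35S:PAP1 day 2 array has the highest 25S value (9.7) and the lowest actin difference (-2.5).

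The genotype effect asks which transcripts differed between 35S:PAP1 and the empty vector across all 5 days. Genes of the late anthocyanin pathway were far higher in 35S:PAP1. DFR (AT5G42800), dihydroflavonol reductase, the first enzyme committed to anthocyanins and tannins, was higher by at least 6.36 ± 0.60 log2 units (SE, 82.1-fold, adjusted p = 0.0146). UF3GT (AT5G54060), which adds xylose to anthocyanins, was higher by 5.5 ± 0.46 (45.3-fold, adjusted p = 0.0111). AT4G14090, the anthocyanin 5-O-glucosyltransferase, was higher by 5.26 ± 0.47 (38.3-fold, adjusted p = 0.0125), and AT5MAT (AT3G29590), the anthocyanin malonyltransferase, by at least 4.62 ± 0.40 (24.6-fold, adjusted p = 0.0124). Each of these differences had the same sign on all 5 days, which the rule for named genes requires.

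The size of that difference varied between days as the levels of both lines moved. DFR read between 10.7 and 12.6 on the 35S:PAP1 arrays, while the empty vector arrays read 4.6, 4.4 and 3.8 on days 1, 2 and 7, then 8.0 and 7.1 on days 8 and 12. Its difference was 7.8, 6.3, 8.6, 4.6 and 4.5 in day order. The empty vector read 3.9 or less for DFR on day 7 and for AT5MAT on days 1, 2 and 7, so those differences are lower bounds. From day 1 to day 2 DFR changed by -1.7 in 35S:PAP1 and -0.2 in the empty vector. AT5MAT changed by -1.9 in 35S:PAP1, while the empty vector read 3.8 and 3.5. These falls in 35S:PAP1 rest on its day 2 array, the one with the -2.5 actin difference. The difference of AT5MAT was 5.7, 4.1, 6.1, 3.2 and 4.0. Over the 4 members of the late anthocyanin list (DFR, UF3GT, UGT78D2 and AT5MAT) the median difference was 6.1, 4.9, 6.6, 3.45 and 4.25, above all random lists on each day (percentile 100). Its medians on days 1, 2 and 7 are lower bounds through AT5MAT.

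The late anthocyanin list passed camera for the genotype effect (adjusted p = 1.24e-13, median 5.06). With an estimated correlation its adjusted p = 0.0500115, just above the threshold, and with fry 0.00442. With members matched by locus alone, chosen after seeing the data, which adds AT4G14090, the adjusted p = 0.0488 with an estimated correlation. Of its members 3 were called over all probe sets and 4 adjusted over the list alone. UGT78D2 (AT5G17050), the flavonoid 3-O-glucosyltransferase, differed by 3.06 ± 0.40 (8.34-fold, adjusted p = 0.0653 over all probe sets). CHIL (AT5G05270), a chalcone isomerase-like protein of the early pathway, gave 2.84 ± 0.39 (adjusted p = 0.0810), and was above the empty vector on all 5 days by 1.0 to 4.0. The flavonol glycosyltransferase UGT78D1 gave 0.44 ± 0.17 (adjusted p = 0.677). AT1G06000, the flavonol 7-O-rhamnosyltransferase, gave 0.32 ± 0.21 (adjusted p = 0.766). BAN, anthocyanidin reductase of the tannin branch, gave 0.08, and HCT, a lignin pathway acyltransferase, gave 0.10. The regulators ATMYC1, TRY and HYH gave 0.26, -0.18 and -0.22, and none of these 5 passed the threshold. BAN, ATMYC1 and HYH read 3.9 or less on several arrays, where a difference could be hidden.

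**Figure D2:**
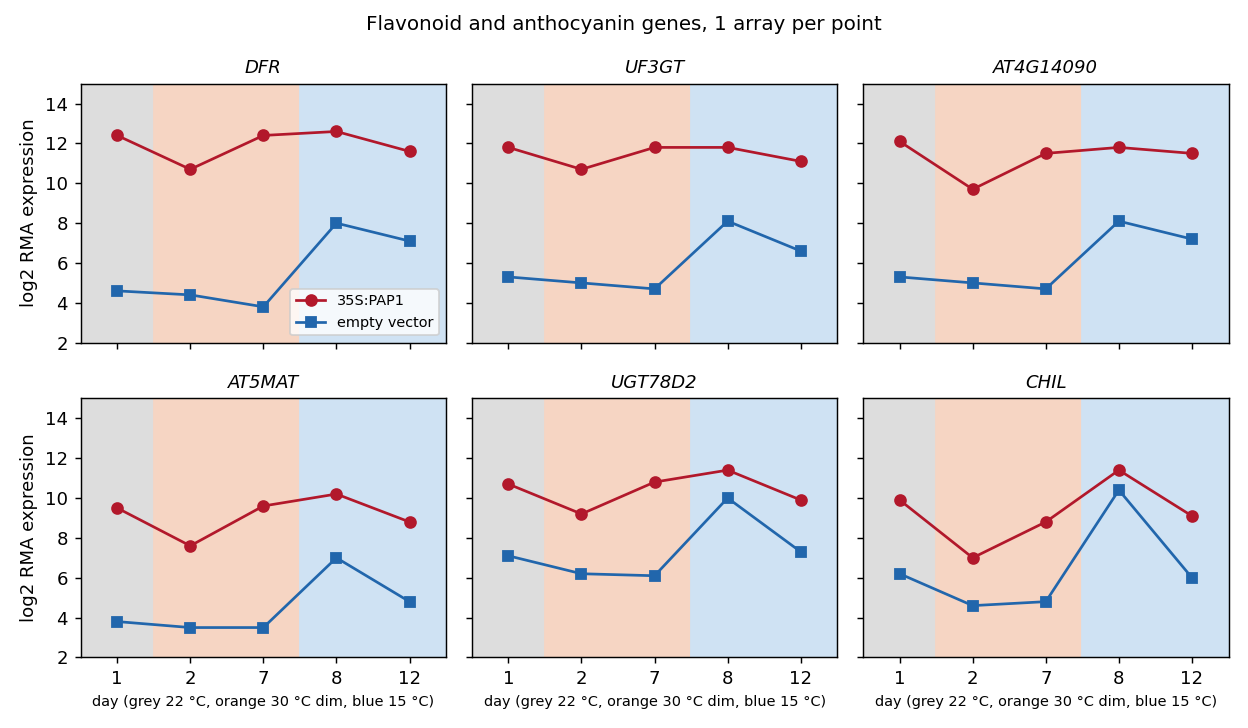
Log2 expression of DFR, UF3GT, AT4G14090, AT5MAT, UGT78D2 and CHIL by day in 35S:PAP1 and empty vector leaves, 1 array per point. DFR stays between 10.7 and 12.6 in 35S:PAP1, while the empty vector rises from 3.8 on day 7 to 8.0 on day 8.

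Outside the pathway 3 named genes were higher in 35S:PAP1. AT4G04750, a sugar transporter family gene, was higher by 1.82 ± 0.18 (adjusted p = 0.0146), AT5G59940 by at least 1.46 ± 0.14 and AT1G20490 by at least 1.18 ± 0.09. CML41 (AT3G50770), a calmodulin-like gene, fell by 1.14 ± 0.13 on the log2 scale (adjusted p = 0.0387). CCOAMT (AT1G67980), a caffeoyl-CoA methyltransferase, fell by at least 0.84 ± 0.10 (adjusted p = 0.0494). The peroxidase list was lower as a set (Prx37, PRX52 and AT5G64120, median -0.88, adjusted p = 2.31e-06). It kept its call with an estimated correlation (adjusted p = 0.0451) and with fry (adjusted p = 0.000293). Of its members 0 were called over all probe sets and 3 adjusted over the list alone. Prx37 read lower in 35S:PAP1 on each day, by -0.5 to -0.6 (3.8 on the 35S:PAP1 day 7 array), whereas AT5G64120 read 0.9 higher on day 1 and lower on the other days. Heat shock (median 0.24, adjusted p = 0.0749), senescence (-0.34, 0.0666), cold response (median -0.04, mean 0.05, 0.580) and light harvesting (-0.16, 0.580) did not pass. The cold average hides opposite differences between the lines, a median of -0.5 on day 1 (percentile 0.005 of random lists) and 1.1 on day 7 (percentile 99.995). The latter rests on the 35S:PAP1 day 7 array, which correlates least with its partner (0.973), and its members part: COR15B 1.8, COR15A 1.2, COR27 1.1, COR47 -0.2 and LTI30 -1.1. Of the other lists, peroxidases lay at percentiles 0.01 to 2.25 on all 5 days, heat shock at 99.95 on day 2 (1.0, on the 35S:PAP1 array with the -2.5 actin difference), light harvesting at 1.79 on day 7 (-0.5), and senescence at 99.4 on day 1 (0.6) and 1.17 to 2.0 on days 7, 8 and 12. Each rests on 1 array per line.

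In all, 18 probe sets differed between the lines, 15 higher and 3 lower in 35S:PAP1. Of these 9 name 1 gene, 1 names several and 8 are not listed in the probe table. The unlisted ones are unnamed here, the largest being higher by 5.42 and 5.38 and the only lower one at -0.72. Without the day block 8 were called, all higher. The count fell to 0 without day 1, 3 without day 2, 3 without day 7 and 0 without day 12, and to 0 without the 35S:PAP1 arrays of days 2 and 7, a setting chosen after seeing the data. Where limma called 0, unadjusted p was under 0.05 for 2053, 1039 and 1272 probe sets in that order. By chance a share of about 0.05 of the 22746 probe sets would do so, and 1039 lies below that share. Such counts, here and below, do not by themselves show remaining differences.

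The comparison of day 2 with day 1 covers the first day of warm dim growth, in both lines together. XTH18 (AT4G30280), a xyloglucan endotransglucosylase of the cell wall, rose by 4.75 ± 0.86 (26.9-fold, adjusted p = 0.0192). EXLA1 (AT3G45970), an expansin-like wall protein, rose by 3.85 ± 0.52 (14.4-fold, adjusted p = 0.00891). AT1G62510, a lipid transfer protein-like gene, rose by 4.40 ± 0.38 (adjusted p = 0.00351), and AT2G20670 by 4.70, AT1G72060 by 3.75, AT2G17660 by at least 3.75, AT3G55840 by 3.70 and AT3G15450 by 3.65. The receptor-like kinase gene AT5G59670 fell by at least 4.3 ± 0.27 (adjusted p = 0.00190). ZIP9, a zinc transporter, and AT2G36885 each fell by 2.70, AT5G55450 by 3.05, AT1G52770 by 2.95, AT2G23910 by 2.85, AT1G73600 by 2.5 and AT5G03350 by 2.4.

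The heat shock list rose on day 2 (adjusted p = 0.0217, median 0.85), with 1 of 3 members called over all probe sets and 3 adjusted over the list alone. Its call was lost with an estimated correlation (adjusted p = 0.551) and with fry (adjusted p = 0.0597). The called member was AT5G48570, a peptidyl-prolyl isomerase gene (1.90 ± 0.46, adjusted p = 0.0428). HSA32 gave 0.85 and the small heat shock gene ATHSP22.0 gave at least 0.70, neither called over all probe sets. ATHSP22.0 read 3.6 on day 1 and 4.7 on day 2 in 35S:PAP1, and 3.4 and 3.7 in the empty vector, and the 35S:PAP1 day 2 array is the one with the -2.5 actin difference. The leucine catabolism genes MCCA and IVD, which are induced by sugar starvation, rose by 2.1 and 1.55. In the cold list COR15A fell by 2.25 and COR47 rose by 1.65, with 2 of 5 members called over all probe sets and 3 adjusted over the list alone. The cold list did not pass (median -0.10, mean -0.55, camera adjusted p = 0.775), and fry pointed up where these point down. In the light harvesting list LHCB4.3 fell by 2.30 and LHCB4.2 rose by 0.90 (median 0.10, mean -0.43, adjusted p = 0.775). Among peroxidases AT5G64120 rose by 2.45 and Prx37 fell by 0.75 (median -0.75, mean 0.20, adjusted p = 0.50). UGT78D1 fell by 1.25 and AT1G06000 by 2.2, while the late anthocyanin list did not pass (median -1.03, adjusted p = 0.388), nor did senescence (median 0.65, adjusted p = 0.388).

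On day 2, 2260 probe sets were called, 1010 higher and 1250 lower than on day 1. The count was 0 without the empty vector day 1 array, 203 without the 35S:PAP1 day 1 array, 677 without the empty vector day 2 array and 0 without the 35S:PAP1 day 2 array. It was also 0 without the 35S:PAP1 arrays of days 2 and 7. In these fits with 0 calls by limma, unadjusted p was under 0.05 for 3970, 3842 and 4997 probe sets. It was 1253 without either day 8 array and 953 without either day 12 array, which give only spread.

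Day 7 was compared with day 1 to show the end of the warm dim period. Among the largest falls were a lipid transfer protein gene, defensin genes and 1 antenna gene. AT5G55450, a lipid transfer protein gene, fell by 5.05 ± 0.39 (adjusted p = 0.00209). PDF1.2 (AT5G44420), a jasmonate-induced defensin, fell by 4.15 ± 0.52 (adjusted p = 0.00691), and PDF1.2b, whose probe set may bind related transcripts, by 3.05. LHCB4.3 (AT2G40100), a minor antenna protein of photosystem II, fell by 3.70 ± 0.41 (adjusted p = 0.00488). AT3G16670 fell by 3.50, AT1G52770 by 3.4, the chitinase family gene AT2G43590 by 3.20 and AT3G05730 by 3.10. HIS1-3 (AT2G18050), a stress-induced linker histone, rose by 2.85 ± 0.30 (7.21-fold, adjusted p = 0.00447). AT1G78070 rose by 3.30, AT1G62510 by 3.10, AT4G36010 by 3.05, AT2G17660 by at least 3.05, AT2G05540 by 2.90, AT1G66760 by 2.85 and AT1G61890 by 2.85.

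None of the 6 lists passed camera on day 7 against day 1. The late anthocyanin list had a median of -0.35 (adjusted p = 0.737). The peroxidase median was -1.05 (camera adjusted p = 0.229, fry 0.000778), with Prx37 and PRX52 called lower and AT5G64120 at 1.4 uncalled. Heat shock had a median of 0.40 and cold response 0.10, each with adjusted p = 0.229, and COR47 rose by 2.45. Light harvesting (-0.15) and senescence (0.15) each had adjusted p = 0.455, and LHCB4.1 gave -0.15 and LHCB4.2 0.50, both uncalled. PYK10 rose by 0.60 (adjusted p = 0.0423).

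Some day 2 changes were smaller on the 35S:PAP1 day 7 array than on that of the empty vector. XTH18 stood 5.1 above day 1 in the empty vector and 1.0 above it in 35S:PAP1. Probe sets that moved the same way by at least 1 log2 unit from day 1 to day 2 in both lines were chosen after seeing the data. The 666 that rose had a median change from day 1 to day 7 of 0.5 in 35S:PAP1 and 1.7 in the empty vector. For the 381 that fell these were -0.9 and -1.4, a smaller reduction. In all 2196 probe sets were called on day 7, 1006 higher and 1190 lower. With each array centred on its median 35.0% were higher, against 45.8% as deposited. The count was 137 without the empty vector day 1 array, 347 without the 35S:PAP1 day 1 array and 216 without the empty vector day 7 array. It was 1335 without either day 2 array, 1368 without either day 8 array and 1099 without either day 12 array. Without the 35S:PAP1 arrays of days 2 and 7 limma called 0, and 6086 had an unadjusted p under 0.05.

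Day 8 against day 7 covers the first day of cool bright growth and gave the most calls of the day contrasts. Among the cold-regulated genes that rose were COR15A (AT2G42540), a chloroplast protein that protects membranes from freezing, by 4.1 ± 0.49 (17.1-fold, adjusted p = 0.00134), and the dehydrin LTI30 (AT3G50970) by 3.90 ± 0.26 (14.9-fold, adjusted p = 0.000223). COR15B rose by 3.10, whereas COR47 gave -0.55 and COR27 -0.30. With 3 of 5 members called over all probe sets and 4 adjusted over the list alone (3 higher, 1 lower), the cold list did not pass camera (adjusted p = 0.157) and passed fry (adjusted p = 0.00791). Of genes in flavonoid metabolism, AT1G06000 rose by 4.35 ± 0.32 (20.4-fold, adjusted p = 0.000318), CHIL by 4.1 ± 0.62 (17.1-fold, adjusted p = 0.00334), UGT78D2 by 2.25 (adjusted p = 0.0378) and UGT78D1 by 1.75 (adjusted p = 0.00345). HYH, a bZIP light-signalling factor, rose by at least 3.30 ± 0.28 (adjusted p = 0.000472).

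Late anthocyanin genes moved mainly in the empty vector on day 8. The day 8 minus day 7 change of DFR was at least 4.2 there and 0.2 in 35S:PAP1, and that of UF3GT 3.4 and 0. In the same order of lines AT5MAT changed by at least 3.5 and 0.6, and UGT78D2 by 3.9 and 0.6. CHIL, outside this list, rose by 5.6 in the empty vector and by 2.6 in 35S:PAP1. Over both lines the list had a median of 2.13 (adjusted p = 0.157), with 1 of 4 members called over all probe sets and 2 adjusted over the list alone.

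Among other genes, AT5G62210 rose by 6.0 ± 0.21 and AT2G23910 by at least 5.30 ± 0.36 (adjusted p = 2.48e-05 and 0.000226), AT3G14395 by at least 3.80 and the glycosyltransferase gene AT2G16890 by at least 3.75. AT5G40450 fell by 5.0 ± 0.18 and AT4G19430 by 4.80 ± 0.15 (adjusted p = 2.48e-05 for both). AT4G27450 fell by 4.15, AT2G05540 by 4.0, AT2G15960 by 3.95, AT1G62510 by at least 3.80, AT5G19120 by 3.60 and AT3G15450 by 3.55. AT5G48570 fell by at least 3.35, MCCA by 2.2 and IVD by 1.35. The antenna genes parted: LHCB4.2 fell by 3.0 and LHCB4.1 by 1.15, while LHCB4.3 rose by 2.1 (light harvesting median -1.15, camera adjusted p = 0.175, fry 0.00791). Heat shock (median -0.25, adjusted p = 0.343), senescence (-0.65, 0.570) and peroxidases (median 0.20, mean -0.23, adjusted p = 0.698) did not pass. PYK10 fell by 0.80 (adjusted p = 0.00648).

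Between days 7 and 8, 5423 probe sets were called, 2569 higher and 2854 lower. Centring moved the higher share from 47.4% to 60.2%. The count was 2739 without the empty vector day 7 array, 2191 without the empty vector day 8 array, 3469 without the 35S:PAP1 day 8 array and 3453 without the 35S:PAP1 arrays of days 2 and 7. With day 2 in place of day 7, whose arrays have the low poly-A controls, it was 6681.

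**Figure D3:**
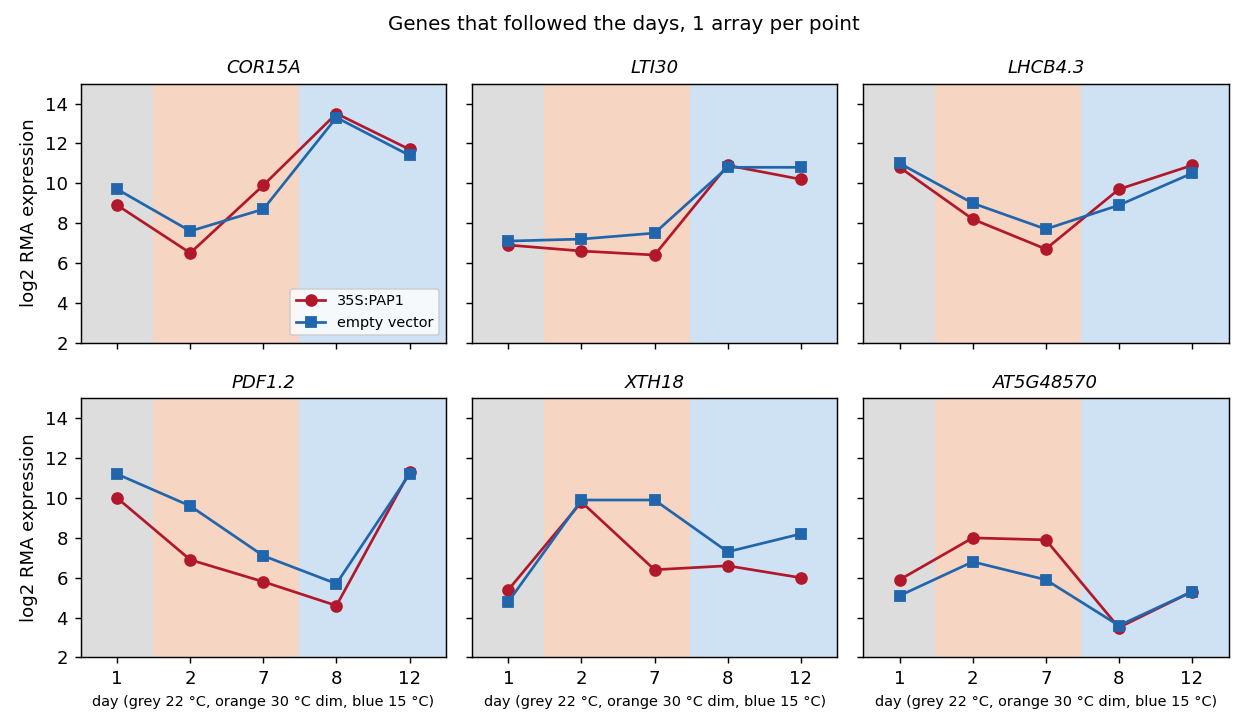
Log2 expression of COR15A, LTI30, LHCB4.3, PDF1.2, XTH18 and AT5G48570 by day in 35S:PAP1 and empty vector leaves, 1 array per point. COR15A peaks on day 8 in both lines (13.5 and 13.3), and XTH18 on day 7 reads 6.4 in 35S:PAP1 and 9.9 in the empty vector.

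By day 12, after further cool bright growth, the largest rises over day 7 included a coumarin enzyme gene, a defensin gene and a chitinase gene. AT3G13610, the feruloyl-CoA 6′-hydroxylase that makes coumarins, read 3.7 and 3.6 on day 7 and rose by at least 5.80 ± 0.59 (55.7-fold, adjusted p = 0.00120). PDF1.2 rose by 4.80 ± 0.52 (27.9-fold, adjusted p = 0.00154), and the chitinase gene CHI (AT2G43570) by 4.40 ± 0.27 (21.1-fold, adjusted p = 0.000238). AT2G44240 rose by at least 5.90, AT5G55450 by 5.85, AT5G55420 by at least 3.95, the TIR-domain gene AT1G57630 by 3.95 and AT5G03350 by 3.90. AT4G19430 fell by at least 5.45 ± 0.15 (adjusted p = 1.38e-05) and HIS1-3 by 3.15 ± 0.30 (adjusted p = 0.00101). AT1G62510 fell by at least 3.95, AT3G24100 by 3.45, AT2G05540 by 3.35, AT2G07718 and AT1G64360 by 3.10 each, and AT4G21870 by 2.85.

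Of the cold list, LTI30 was above day 7 on day 12 by 3.55 and COR15A by 2.25, with COR47 at -0.90 called lower (list median 1.25, adjusted p = 0.331). LHCB4.3 rose by 3.50 (light harvesting median -0.10, mean 0.95, adjusted p = 0.685). Prx37 rose by at least 1.90 and PRX52 by 2.35 (peroxidase median 1.90, camera adjusted p = 0.0530, fry 9.51e-05). HYH rose by at least 1.15 and PYK10 fell by 0.75. The late anthocyanin (median 0.43, adjusted p = 0.545), heat shock (-0.15, 0.376) and senescence (0.95, 0.331) lists did not pass. Altogether 3216 probe sets were called, 1610 higher and 1606 lower. The count was 1459 without the empty vector day 7 array, 685 without the empty vector day 12 array and 855 without the 35S:PAP1 day 12 array. Without the 35S:PAP1 arrays of days 2 and 7 limma called 0, and 5978 had an unadjusted p under 0.05.

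The regime contrasts set days 2 and 7 against days 1, 8 and 12 within each line. In 35S:PAP1 Hop3 (AT4G12400), a co-chaperone linking HSP70 and HSP90, was higher in the warm dim regime by at least 3.42 ± 0.26 (10.7-fold, adjusted p = 0.0161), and the small heat shock gene AT5G51440 by at least 2.90 ± 0.33 (7.46-fold, adjusted p = 0.0360). AT1G62510 was higher by at least 3.75, AT2G05540 by 3.03, AT2G46250 by at least 2.65 and AT2G42040 by 1.82. AT2G36885 fell by 3.23, AT5G19750 by 2.12, AT1G62780 by 1.97, AT3G44970 by at least 1.68, the carboxypeptidase gene scpl35 by 1.65 and the histone gene HTB2 by 1.52. The heat shock list was higher (median 0.63, adjusted p = 0.0254), with 0 members called over all probe sets and 2 adjusted over the list alone. With an estimated correlation its adjusted p = 0.299, and with fry 0.0848. HSA32 read 5.5 and ATHSP22.0 4.7 on the 35S:PAP1 day 2 array, the array with the actin difference of -2.5, and 4.3 and 3.9 on day 7, against 4.4 to 4.5 and 3.6 to 3.8 on the bright days, so for these genes the difference rests on that 1 array. AT5G48570 read 8.0 and 7.9 on days 2 and 7. The late anthocyanin list had a median of -0.66 (adjusted p = 0.739). Cold response (-1.60, 0.739), peroxidases (-0.92, 0.739), light harvesting (median 0.47, mean -0.37, 0.889) and senescence (median 0.25, mean -0.11, 0.806) did not pass.

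In the empty vector AT1G62510 was higher in the warm dim regime by at least 4.78 ± 0.55 (27.5-fold, adjusted p = 0.0191). The peroxidase gene AT4G33420 was higher by 3.35, AT2G05540 by 3.35, the defensin-like PDF1.4 by at least 3.03, AT5G51390 by 2.48 and AT2G42040 by 2.32. Hop3 was higher by at least 1.87 (adjusted p = 0.0287) and IVD by 1.88 (adjusted p = 0.0356). AT3G44450 and AT3G52740, which encode inhibitors of blue-light cryptochromes, fell by 3.35 ± 0.59 and 2.28 ± 0.37 (adjusted p = 0.0468 and 0.0382). AT5G59670 fell by at least 3.53, AT2G36885 by 2.63, AT1G68570 by 2.18 and HTB2 by 2.13. The late anthocyanin list was lower in this line (median -1.90, adjusted p = 0.0450), with 0 of 4 members called either way. With an estimated correlation its adjusted p = 0.713, and with fry 0.373. Its median level was 4.95 on day 1, 4.7 and 4.25 on days 2 and 7, and 8.05 and 6.85 on days 8 and 12. The contrast thus rests mainly on the rise on the cool bright days, with day 1 close to the warm dim days. Heat shock (0.35, 0.314), cold response (-2.22, 0.314), light harvesting (0.52, 0.794), senescence (0.15, 0.713) and peroxidases (median -0.88, 0.713) did not pass.

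These contrasts called 55 probe sets in 35S:PAP1 (36 higher, 19 lower) and 267 in the empty vector (160 higher, 107 lower). In 35S:PAP1 centring moved the higher share from 65.5% to 47.6%, and the count was 12, 0, 14, 0 and 0 without day 1, 2, 7, 8 or 12. In the empty vector it was 16, 0, 0 and 0 without day 1, 2, 7 or 8. Without the 35S:PAP1 day 7 array the 35S:PAP1 contrast called 151 probe sets, and without its day 2 array 0. Where limma called 0 on leaving out a day, 1978 to 3365 probe sets in 35S:PAP1 and 2374 to 3913 in the empty vector had an unadjusted p under 0.05.

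The interaction asks whether the 35S:PAP1 effect itself differed between the warm dim and the bright days. With limma 0 probe sets passed, 2052 had an unadjusted p under 0.05, and the smallest adjusted p was 0.378. The late anthocyanin list had a median of 1.41, a larger difference between lines on the warm dim days (adjusted p = 0.108). By day its median difference read 6.1 on day 1, 4.9 and 6.6 on days 2 and 7, and 3.45 and 4.25 on days 8 and 12. Day 1 lay between the warm dim days, so the contrast rests on the smaller differences on days 8 and 12. DFR gave at least 1.82 ± 1.15 (adjusted p = 0.657), UF3GT 1.5 ± 0.84 and Hop3 1.55 ± 0.36 (adjusted p = 0.461). Hop3 read 3.9 or less on the bright days in both lines, so its difference there was not measured. Heat shock (0.43, 0.108), light harvesting (-0.23, 0.130), senescence (-0.87, 0.244), cold response (0.15, 0.626) and peroxidases (-0.03, 0.867) did not pass. Only 9% of simulated differences of 1 log2 unit were recovered by this test, so differences of that size were mostly not detectable.

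Most changes called on entering the warm dim regime were called the opposite way on day 8, and fewer were on day 12. Of the 2260 probe sets called on day 2 against day 1, 1453 (64.3%) were called the opposite way on day 8 against day 7 and 18 the same way, where independent lists would share 267.9 in opposite directions. On day 12 against day 7, 996 (44.1%) were opposite and 16 the same way, against 159.8. The log2 changes correlated across probe sets at -0.64 and -0.51. AT1G62510 rose by 4.40 and then fell by at least 3.80, and AT2G23910 fell by 2.85 and then rose by at least 5.30. These comparisons share no array but use 1 estimate of spread, and probe sets are not independent replicates. No array is of plants kept in the first regime, so regime cannot be told apart from plant age and day.

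Both lines moved alike in most steps. Across probe sets, the changes in 35S:PAP1 and the empty vector correlated at 0.697 from day 1 to day 2, 0.499 from day 1 to day 7, 0.709 from day 7 to day 8 and 0.732 from day 7 to day 12. From day 2 to day 8, which leaves out the day 7 arrays, the correlation was 0.851, and from day 2 to day 7 it was 0.352. COR15A rose by 4.6 from day 7 to day 8 in the empty vector and by 3.6 in 35S:PAP1. The lines have 1 array per day, so these correlations have no replicate error.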

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

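The tests of exchanged arrays, of mixed RNA, of RNA breakdown on the 35S:PAP1 day 7 array and of a lasting effect on anthocyanin genes were chosen only after the result was seen.

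Of 44 measures tested for an array far from the others of its group, 7 had one. The rate of about 1 in 20 by chance holds for independent groups of replicates. Here the arrays of a group are of different days and the measures overlap, so the count cannot be set against that rate. The GAPDH 5′ minus 3′ difference was -0.2 on the empty vector day 12 array. AT5G59940 differed between the lines by at least 2.1 on day 7, far from the other days. AT4G14090 read 9.7 on the 35S:PAP1 day 2 array, the lowest for that line. The poly-A control median was 3.8 and 3.85 on the empty vector and 35S:PAP1 day 7 arrays. The actin difference was -2.5 on the 35S:PAP1 day 2 array, and the lines correlated at 0.973 on day 7. The 25S ribosomal RNA probe set, outside the main measurement, read 9.7 on the 35S:PAP1 day 2 array.

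The genotype count was set against other divisions of the 10 arrays into 5 and 5. Of 100 divisions drawn from 126, 3 gave at least 18 probe sets, the real one included, and the highest other gave 127. The 2 larger divisions part the lines on days 2, 7 and 12 only. With day as a block both are the same fit with opposite sign, the difference between the lines on those days. They are thus no grouping apart from the lines. Day pairs the arrays, so the divisions to compare are the 16 that part every day, where the real one gave 18 and the highest other 0. These are too few for a share under 0.05.

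A first pattern is the 35S:PAP1 day 7 array, on which changes seen on day 2 were reduced, more for the 666 probe sets that had risen (0.5 against 1.7 in the empty vector) than for the 381 that had fallen (-0.9 against -1.4). An exchange with an array of another day is argued against by its poly-A controls, which lie 0.05 from those of the other day 7 array; an exchange of tissue before labelling is not covered. Breakdown of RNA cannot be told apart: its mean actin and GAPDH 5′ minus 3′ difference of -0.75 is above only the 35S:PAP1 day 2 array (-1.45) and the empty vector day 12 array (-0.8), which has the low GAPDH value, and the other 7 arrays span -0.65 to -0.45, while its actin difference is -1.5 against -1.4 to -1.2. Mixture with RNA of day 1 or day 12 would have to supply a median of 79.2% or 48.4%, while dimmed probe sets allow 6.70% and 7.18%, narrowly for day 12 (upper quartile allowed 11.9%, lower quartile needed 12.6%); for day 8 the 16.5% allowed and 54.0% needed overlap in their spread and cannot be told apart. A different response of 35S:PAP1 plants by day 7 may remain, as may a difference in the plants or hour sampled, and with 1 array neither was tested.

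The next pattern is the dip of late anthocyanin genes in 35S:PAP1 on day 2, a median of -1.6 from day 1, on the array with signs of RNA breakdown. Random lists of similar brightness that were stable in the empty vector had medians of -0.6 to 0.3 on this array. The anthocyanin list lay at percentile 0.02 among them, a larger fall than unrelated probe sets showed. Its members move nearly as 1 (estimated correlation 0.948), so the random medians spread too little. UGT78D2 also changed by -0.9 in the empty vector, outside the limit for stable probe sets. The comparison thus cannot decide whether general breakdown was the whole cause. A lasting effect of the warm dim regime could not be settled, since the change by day 7 was 0.05, or -3.125% of that on day 2, and rests on the day 7 array that stands apart. A brief response to the warm dim regime may remain as a hypothesis, as may a breakdown that hits these transcripts more than others.

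The last pattern is the large count between days 7 and 8, given that both day 7 arrays lack the poly-A signal and may have been labelled separately. Of 4391 probe sets that moved by at least 1 log2 unit from day 7 to day 8 in the empty vector, 94.6% moved the same way from day 2 to day 8 in 35S:PAP1, arrays that have the poly-A signal. This argues against separate labelling as the whole cause. A part in the size of single changes stays open, because labelling and day 7 coincide. The change of regime stays open as the biological explanation.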

How the results depend on the processing

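The settings that leave out the 35S:PAP1 day 2 or day 7 arrays, put day 2 in place of day 7, add rounding noise or match list members by locus alone were chosen only after the result was seen.

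Of 144 recomputed counts, shares and correlations, 85 stayed within 1.5 times their value or their spread and 59 moved. Of 1824 recomputed values of named genes 1449 kept direction and threshold, 375 lost the threshold and 0 reversed. The genes were named for passing the threshold and, for genotype and day contrasts, for a shared sign. Reversals were thus unlikely from the outset. Leaving out 1 array of a day outside a day contrast gives the same fit as leaving out that day, so both tallies count some fits repeatedly. With only probe sets naming 1 gene, which tests fewer, the counts were 9 (genotype), 1157 (day 2 against day 1), 1100 (day 7 against day 1), 2892 (day 8 against day 7), 1752 (day 12 against day 7), 27 (regime in 35S:PAP1) and 130 (regime in the empty vector). Without the day block the genotype count was 8. With a trended robust prior the regime counts were 19 and 111, and without the dimmest probe sets the 35S:PAP1 one was 6; the cause was not tested. Leaving out each day or array, with fewer arrays, gave 0 to 13 for genotype, 0 to 2749, 137 to 1567, 2191 to 4970 and 685 to 2591 for the day contrasts in order, 0 to 14 and 0 to 331 for the regimes, and 0 for the interaction. Leaving out the 35S:PAP1 arrays of days 2 and 7 gave 0 (genotype), 0, 0, 3453 and 0 for the day contrasts; for the 35S:PAP1 regime, 151 without day 7 and 0 without day 2. Day as a random block gave 45 and 307 for the regimes, within 1.5 times. The interaction stayed at 0 in every setting run.

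Of 144 list tests 130 kept their side of the threshold. With an estimated correlation, calls ended for late anthocyanin genes by genotype (adjusted p = 0.0500115) and by regime in the empty vector (0.713), and for heat shock on day 2 (0.551) and by regime in 35S:PAP1 (0.299). With fry, calls ended for heat shock on day 2 (0.0597) and by regime in 35S:PAP1 (0.0848) and for late anthocyanin genes by regime in the empty vector (0.373). Calls appeared with fry for peroxidases on day 2 (0.00752), day 7 (0.000778) and day 12 (9.51e-05), and for cold response and light harvesting on day 8 (0.00791 each); fry does not compare a list with other genes. Matching by locus alone added genotype calls for heat shock (0.0479) and senescence (0.0499), both lost with an estimated correlation (adjusted p = 0.341 each) and with fry (0.381 each). Senescence gained no member there, and its call comes from the adjustment over the lists alone. Brightness limits dim genes: no detection call was used.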

Other observations

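All tests of gene families were chosen only after the data were seen, as 36 families of at least 7 probe sets sharing a symbol prefix or an organelle genome. With an estimated correlation 0 of them passed in any comparison, so the values stand as descriptions; the adjusted p-values are from camera at the preset correlation.

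Autophagy genes (ATG, 8 members, mostly ATG8 genes that coat autophagosomes) were higher on day 2 than on day 1 (median 0.70, adjusted p = 0.00204; 0.769 with an estimated correlation), with 3 called, and lower on day 8 than on day 7 (median -1.05, adjusted p = 7.34e-05; 0.620 with an estimated correlation), with 8 of 8 called. ATG8E rose by 1.60 ± 0.33 on day 2 and fell by at least 2.25 ± 0.33 on day 8, and ATG8B rose by 1.15 and fell by 1.05. Plant U-box ubiquitin ligase genes (PUB, 9 members) were higher on day 2 (median 0.95, adjusted p = 0.00468; 0.769 with an estimated correlation), with PUB22, PUB25, PUB26 and PUB43 called. PUB25 rose by 1.95 ± 0.26 (adjusted p = 0.00894). They were also higher on day 7 than on day 1 (median 1.05, adjusted p = 0.0114; 0.690 with an estimated correlation), with 2 called.

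Genes named nad, for subunits of mitochondrial complex I (8 members), were higher on day 7 than on day 1 (median 1.35, adjusted p = 0.000518; 0.393 with an estimated correlation), with 6 called. They were lower on day 12 than on day 7 (median -1.33, adjusted p = 0.000250; 0.313 with an estimated correlation), with 5 called. Both day 7 arrays are the ones with poly-A control medians of 3.8 and 3.85. The gene nad4L rose by 2.05 ± 0.15 by day 7 and fell by 2.35 ± 0.15 by day 12. Glutamate receptor-like channel genes (GLR, 8 members) were higher on day 12 than on day 7 (median 1.00, adjusted p = 0.00281; 0.313 with an estimated correlation), with 5 called and GLR2.8 highest at 2.35 ± 0.37. Plastid-encoded genes (69 members) had lower differences between the lines on the warm dim days than on the bright days (median -0.27, adjusted p = 1.43e-05; 0.908 with an estimated correlation), with 0 called. Their median level was 9.3 on the 35S:PAP1 day 2 array, the array with the -2.5 actin difference, and 9.9 to 10.4 on the other arrays.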
